A study of Homo sapiens with 12 samples.

How the data were processed

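Total RNA and small RNA were sequenced from parental HCT116 cells, a human colorectal carcinoma line, and from HCT116oxR, a line derived from them by growth in rising doses of oxaliplatin, a platinum drug that forms adducts with DNA. Each line gave 3 total RNA libraries and 3 small RNA libraries, so that 12 libraries were analysed. Per the labels, the drug was raised through steps of 0.1, 0.5, 1.0 and 2 µmol/L to 5 µmol/L, and the last step was kept for 1 year. The labels describe the 3 replicates of each line as cultures grown and harvested separately, from 1 resistant line and its parent, so the p-values measure the spread between cultures and not between independently derived resistant lines. RNA with an integrity number above 8.0 went into library preparation per the labels' protocols.

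The values deposited by the authors were raw counts, in 1 table of 54261 genes for total RNA and 1 table of 2588 mature miRNAs for small RNA. Every column of values belonged to a sample and was used. Reads were aligned to GRCh38 with HISAT2 for total RNA and with BWA for small RNA per the submitters' processing notes. Their versions, the tool that counted reads, the annotation release, the use of strand and the treatment of reads with several matches are not given in the sources used here. Reads from overlapping or antisense genes and from near-identical gene copies may therefore be shared between entries of the deposited count tables, and such genes are named as uncertain. Gene classes and positions came from the NCBI gene table for GRCh38, to which 51452 of the 54261 genes were matched (45971 by symbol, 3682 by gene number and 1799 by an older symbol). A further 2809 genes had no match and entered the gene tests without a class or position.

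Total counts per library were 11950069 to 13558077 for total RNA and 16089595 to 18147051 for small RNA. Counting error was small at this depth for genes with many counts, while genes with few counts were limited by it. PCR duplicates could not be removed from counts, so limits derived from counts cover counting error only. Where every library of a line had 0 counts, the fold was computed against a floor of 3 counts in each library and is given as a lower bound. Where a line had 1 to 3 counts in all, the ratio of CPM (counts scaled to the library total) is given with an exact 95% binomial counting interval. No 2 libraries of a line agreed within sampling noise, with a chi-square per degree of freedom of 2.21 or more in total RNA and 5.40 or more in small RNA, so each was kept as 1 replicate.

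The lines were compared in R 4.3.3 with edgeR 4.0.16, separately for the 2 library kinds. Features with too few counts were removed with filterByExpr (at least 10 counts in a library of median size and 15 in all), library sizes were scaled with TMM factors, and the quasi-likelihood F test with robust dispersion was used, 2-sided. Adjusted p-values are Benjamini-Hochberg values over all features tested, with a threshold of 0.05. This left 17511 genes and 975 miRNAs. Fold changes are log2 ratios of HCT116oxR over parental cells. Errors given with them are standard errors of the log2 fold change (SE). Each was computed as the absolute log2 fold change over the square root of the F statistic. Such SEs are approximate and can be too small for large changes with few counts in a line. Levels are TMM-scaled CPM with the SD over 3 libraries. Among total RNA genes the common biological coefficient of variation was 4.77%, and among miRNAs it was 12.4%.

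Gene groups were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over all lists with at least 3 tested members. The same test with an estimated correlation was run beside it, as was fry, which tests whether a list's members move one way on balance without comparing them with other genes. The 36 gene lists and 23 miRNA lists were drawn from general knowledge of platinum drugs, colorectal cancer cells and other cell types. Members were counted as higher or lower at the adjusted p over all features, and also adjusted over the list alone. Protein-coding genes were grouped by chromosome and by windows of 10 Mb holding at least 10 tested genes, and each group was tested with camera against all other genes. The tests, the lists, the alternatives named below and the rule for naming genes were fixed before the data were examined.

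Genes were named by the following rule. In total RNA these were the 10 genes with the largest and the 10 with the smallest log2 fold change among those past the threshold, with an average log2 CPM of at least 2 and with every library of one line above every library of the other. The 6 highest and 6 lowest lncRNAs by the same criteria, at an average log2 CPM of at least 0, were added, as were up to 4 members past the threshold of each list described. SLC31A1, ATP7A, ATP7B, ABCC2, ABCB1, ERCC1, CDKN1A and MDM2 were named whatever their test. In small RNA the 8 highest and 8 lowest miRNAs with an average log2 CPM of at least 4 were taken, and miR-21-5p, miR-34a-5p, miR-200c-3p, miR-203a-3p and miR-31-5p were named whatever their test. A few further genes are named in the text as chosen after their values were seen.

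The gene, list and window tests were tested on simulated counts drawn from the libraries' own means and sizes. In simulated total RNA with 17441 genes, edgeR called 46% of genes changed by 1.25-fold, 74% of those changed by 1.5-fold, 93.9% of those changed by 2-fold and 100% of those changed by 4-fold, with 6 false calls. In simulated small RNA with 968 miRNAs the shares were 17.8%, 56.5%, 100% and 100%, with 4 false calls. A list shifted by 0.5 (log2) was called in both simulations, with 1 other list called in total RNA and 0 in small RNA. A window shifted by -0.5 was called lower, and 0 of the other windows were called. The shifted lists and the shifted window were called with an estimated correlation too. Simulated genes were drawn independently of each other with 1 common dispersion per library kind. The simulations therefore do not show how often the preset test calls groups of correlated genes.

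Alternatives were scaling by RLE factors, by upper quartile factors and by total count alone, a looser and a stricter filter on low counts, DESeq2 1.42.0 and limma-voom, a block for the replicate number, leaving out each library in turn, a threshold of 0.01, a test against a fold of 1.5 (glmTreat), library sizes without the 10 most abundant features, and windows of 5 Mb. A fit without the genes in the windows that passed was added after the data had been seen. miRNA seed sites in 3' untranslated regions were planned and not analysed here, since no transcript sequences were used.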

Results

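Total RNA and small RNA were compared between parental HCT116 colorectal carcinoma cells and HCT116oxR cells, which had been selected in oxaliplatin up to 5 µmol/L. There were 3 libraries per line for each kind of RNA, with 11950069 to 13558077 counts in the total RNA libraries and 16089595 to 18147051 in the small RNA libraries. In total RNA the 10 most abundant genes held 5.02% to 5.68% of the counts of a library. In small RNA the 10 most abundant miRNAs held 71.4% to 74.96%, and miR-21-5p alone held 49.4% to 52.8%. Libraries of the same line correlated at 0.987 to 0.989 (Pearson's r of log2 CPM across genes) and libraries of different lines at 0.955 to 0.958 in total RNA. In small RNA the same-line values were 0.986 to 0.989 and the different-line values 0.954 to 0.963. The first principal component separated the lines and held 91.2% of the variance of the most variable genes in total RNA and 68.6% in small RNA.

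The first question was which transcripts differ between cells selected in oxaliplatin and their parent. DHRS2, which encodes a short-chain dehydrogenase, fell from 1937 ± 40.1 to 11.1 ± 0.683 CPM (mean ± SD, n = 3 per line), 173-fold lower in HCT116oxR. TTN, the gene of the giant sarcomere protein titin, fell from 2595 ± 11.4 to 1.86 ± 0.960 CPM, 1369-fold. VIM, which encodes the intermediate filament vimentin of mesenchymal cells, fell 44.9-fold from 114 ± 9.33 to 2.53 ± 0.213 CPM, and CXCL8, the gene of the neutrophil chemokine interleukin-8, fell 29.3-fold from 61.5 ± 1.94 to 2.09 ± 0.459 CPM. In the other direction, SYK, which encodes a non-receptor tyrosine kinase of immune receptor signalling, rose 34.5-fold from 0.775 ± 0.107 to 27.0 ± 3.32 CPM. DRD1, the dopamine D1 receptor gene, had 0 counts in each parental library and 126, 88 and 82 counts in the HCT116oxR libraries, which put it at least 31.2-fold higher.

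These genes were among 7721 of 17511 tested genes that changed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted), 3906 higher and 3815 lower in HCT116oxR. At least 2-fold changes numbered 1525, with 854 higher and 671 lower. Every library of one line lay above every library of the other for 8837 genes, 50.5% of those tested, where chance gives 10%. Tested against a fold of 1.5 instead of no change, 1430 genes remained past the threshold.

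The further genes with the largest rises were FAM49A (log2 fold change 6.58 ± 0.31, SE, adjusted p = 6.65e-41), LARGE (6.36 ± 0.35), ZMAT1 (5.52 ± 0.33), TIMP3 (5.19 ± 0.37), CYB5R2 (4.30 ± 0.27) and SLC6A20 (4.23 ± 0.26). TIMP3 encodes an inhibitor of matrix metalloproteinases, LARGE a glycosyltransferase that modifies dystroglycan, and SLC6A20 a proline transporter. The further genes with the largest falls were TNFRSF9 (-6.90 ± 0.25, adjusted p = 6.27e-47), which encodes the costimulatory receptor CD137, CSMD3 (-6.38 ± 0.29), HYDIN and DAPP1. HYDIN, a gene of motile cilia, had 811 counts over the parental libraries and 1 over the HCT116oxR libraries, a ratio of CPM of 849 with a 95% counting interval of 152 to 33558. DAPP1, an adaptor of phosphoinositide signalling, had 490 and 2 counts, a ratio of 256 with an interval of 70.6 to 2123. Several of these genes overlap others in the annotation (TTN with TTN-AS1, VIM with VIM-AS1, TIMP3 with SYN3, CYB5R2 with PPFIBP2), and HYDIN has a near-identical copy, HYDIN2, so their counts are uncertain to that extent.

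**Figure D1:**
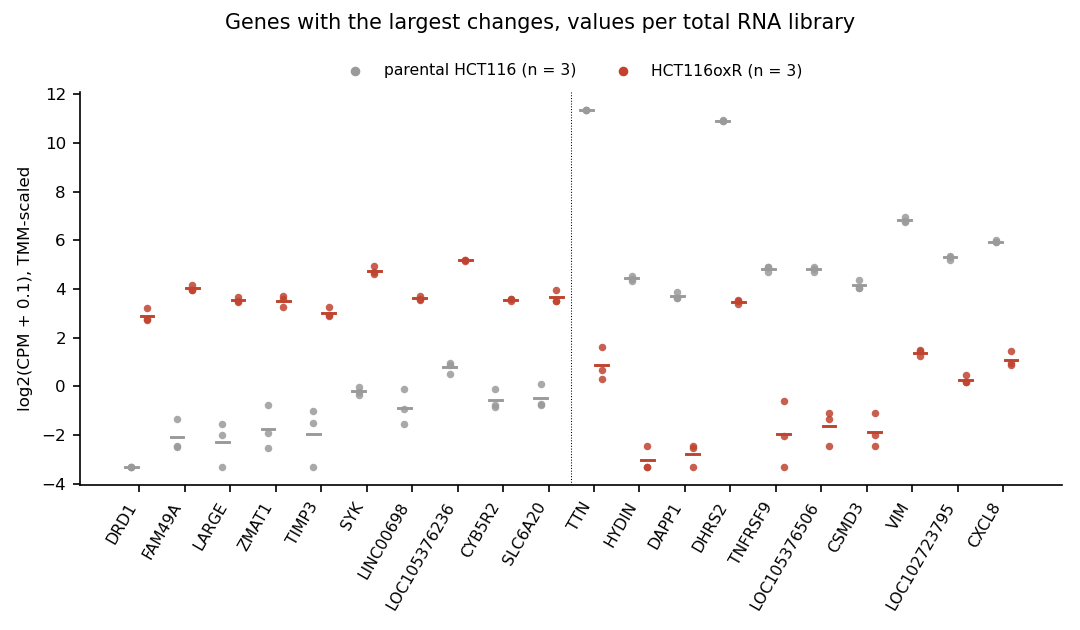
TMM-scaled level of each of the 20 genes with the largest changes, as log2 of CPM plus a pseudocount of 0.1, in the 3 parental libraries (grey points) and the 3 HCT116oxR libraries (red points), with the mean of the log2 values as a bar. Genes left of the dotted line were higher in HCT116oxR and genes right of it lower. The points of the lines do not overlap for any of the 20 genes because the rule for naming genes required it.

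The series asks about non-coding RNAs, so genes annotated as lncRNA or antisense RNA were compared as a group. LINC00698 rose from 0.498 ± 0.301 to 12.2 ± 0.674 CPM (log2 fold change 4.57 ± 0.28, SE, n = 3 per line) and LOC105376236 from 1.65 ± 0.269 to 36.4 ± 0.735 CPM (4.45 ± 0.16). LINC01366 had 0 counts in the parental libraries and was at least 7.95-fold higher in HCT116oxR. LOC646736 had 1 count over the parental and 229 over the HCT116oxR libraries, a ratio of CPM of 219 with a 95% counting interval of 38.9 to 8682. Among those that fell were LOC102723795 (39.4 ± 2.204 to 1.13 ± 0.153 CPM, -5.12 ± 0.17), LOC105376506 (-6.72 ± 0.24) and the stress-induced LUCAT1 (26.1 ± 1.46 to 2.93 ± 0.795 CPM, -3.16 ± 0.16).

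Of 1882 tested lncRNAs, 623 changed, 256 higher and 367 lower (edgeR, adjusted over all genes), and 565 changed when adjusted over the list alone, 234 higher and 331 lower. At least 2-fold changes numbered 129 higher and 174 lower. The remaining lncRNAs named by the rule rested on few counts. LOC105375659 had 1 and 69 counts over the parental and HCT116oxR libraries (ratio 65.9, interval 11.4 to 2642) and LOC101928100 had 2 and 64 (30.6, 8.13 to 258). In the other direction LOC105378094 had 83 and 1 (86.8, 15.2 to 3471), LOC105379514 had a ratio of 52.8 (14.3 to 442.3) with 2 counts in HCT116oxR, and LOC105370918 (-5.05 ± 0.56) and LOC107985243 (-4.43 ± 0.63) fell. Of the 12 lncRNAs named by the rule, 5 overlap another gene (LOC105376506 with ANO9, LOC105375659 with NIPAL2, LOC101928100 with KLRK1, LOC105370918 with MINAR1, LOC107985243 with LINC02789). Without stated strand, their reads cannot be told apart from those of the partner.

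Among lncRNAs described in cancer, 21 of 53 tested rose and 10 fell, and adjusted over the list alone the numbers were also 21 and 10. The list did not pass as a group (camera adjusted p = 0.0749). H19, the imprinted lncRNA next to IGF2, rose by 2.82 ± 0.54 (log2), and CASC8 on chromosome 8 rose by 1.80 ± 0.35, while PCAT7 fell by 1.45 ± 0.20. H19, CASC8 and PCAT7 overlap other annotated genes. Among transcripts that host miRNAs, 8 of 21 rose and 6 fell (9 and 8 adjusted over the list alone, camera adjusted p = 0.430). GABRE, a GABA receptor subunit gene whose introns carry miR-224 and miR-452, had 0 counts in parental cells and was at least 10.96-fold higher in HCT116oxR. MIR17HG rose by 0.96 ± 0.18, MIR22HG fell by 1.35 ± 0.19 and MIR31HG fell by 1.20 ± 0.33. MIR22HG lies on chromosome 17 in the window from 0 to 10 Mb, which passed as lower (described below).

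Lists of genes fixed from general knowledge showed which cell functions moved together. The NF-kB and chemokine genes were the list with the lowest median. Of 18 tested members 15 fell and 2 rose, 13 of them by at least 2-fold downward, with a median log2 fold change of -1.96 (camera adjusted p = 8.96e-14). The call held with an estimated correlation (adjusted p = 0.0186). Beside CXCL8, IL1A (-3.54 ± 0.54) encodes interleukin-1 alpha, BIRC3 (-3.36 ± 0.06) an inhibitor of apoptosis that is a classic NF-kB target, and LCN2 (-3.05 ± 0.36) the siderophore-binding lipocalin. Adjusted over the list alone, 15 members were lower and 2 higher.

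NRF2 targets and glutathione synthesis genes, the antioxidant programme driven by the transcription factor NRF2, fell as a group. Of 27 tested members 20 fell, 2 rose and 5 did not pass, with a median log2 fold change of -0.52 (camera adjusted p = 4.39e-14, and adjusted p = 0.0186 with an estimated correlation). Adjusted over the list alone, 20 were lower and 2 higher. OSGIN1 fell from 38.0 ± 2.67 to 13.9 ± 0.217 CPM (-1.45 ± 0.10, SE), SRXN1, the gene of sulfiredoxin, from 280.7 ± 12.6 to 122 ± 7.57 CPM (-1.21 ± 0.04), and AKR1C3 from 5.61 ± 0.357 to 1.71 ± 0.190 CPM (-1.71 ± 0.27). AKR1C3 has close paralogs that could share its reads. AKR1B10, an aldo-keto reductase gene, had 62 counts over the parental and 3 over the HCT116oxR libraries, a ratio of CPM of 21.6 with a counting interval of 7.06 to 108. SLC7A11, the cystine importer gene, fell by 1.19 ± 0.03. GCLC (-1.05 ± 0.05) and GCLM (-0.91 ± 0.05), which encode the subunits of the rate-limiting enzyme of glutathione synthesis and were chosen after their values were seen, fell too.

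**Figure D2:**
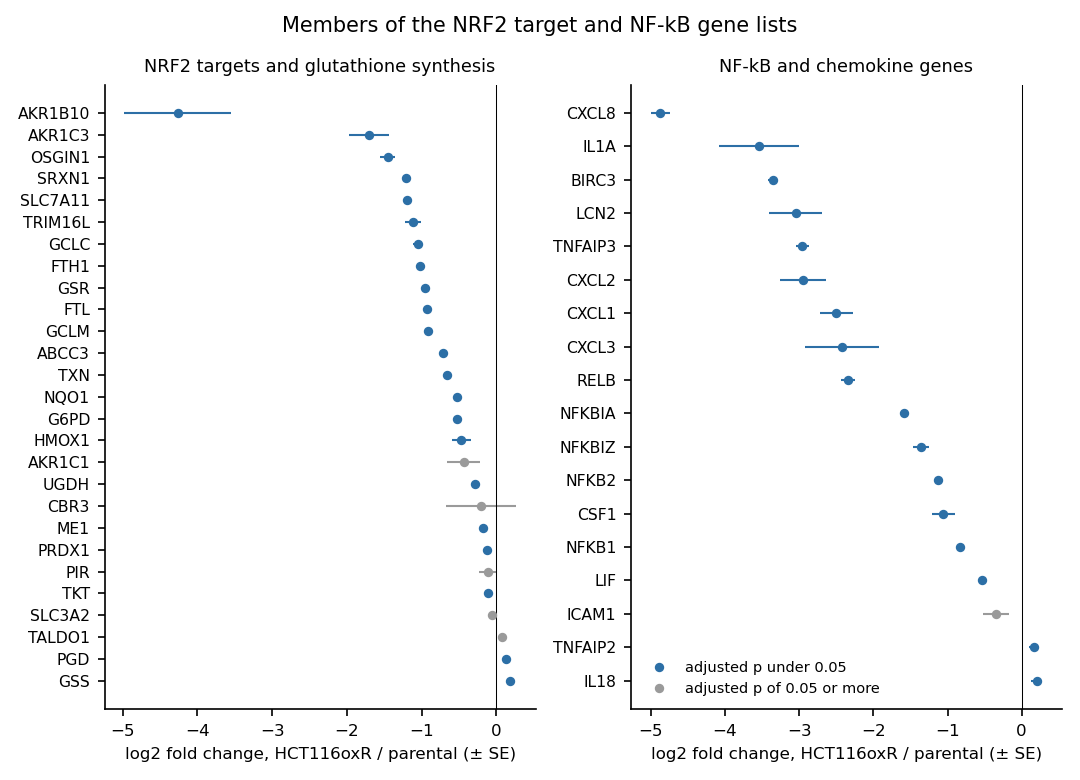
Log2 fold change in HCT116oxR over parental cells (horizontal axis, point, with its SE as a bar, n = 3 libraries per line) of each tested member of the NRF2 target list (left, 27 genes) and of the NF-kB and chemokine list (right, 18 genes). Blue points passed the adjusted threshold over all genes, and 20 of 27 and 15 of 18 members fell.

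Further lists passed in the preset test and were lost with an estimated correlation. The estimate lay below the preset 0.01 for apoptosis regulators (-0.0245), epithelial junction genes (-0.0250) and cell cycle genes (-0.00882). It lay above 0.01 for the other gene lists lost. A higher correlation therefore cannot account for the loss of the lists with the lower estimates. Metallothioneins, the cysteine-rich metal-binding proteins, fell in 3 of 4 tested members (camera adjusted p = 0.00317, adjusted p = 0.242 with an estimated correlation), and 3 fell adjusted over the list alone. MT2A fell from 263 ± 22.7 to 109.6 ± 11.5 CPM (-1.26 ± 0.09), MT1X by 1.16 ± 0.12 and MT1E by 0.53 ± 0.05, and these near-identical family members may share reads. Of 31 apoptosis regulators 15 fell and 6 rose (16 and 6 adjusted over the list alone, camera adjusted p = 0.00459). That call was lost too, with adjusted p = 0.141 with an estimated correlation. The death receptor genes TNFRSF10B (-1.06 ± 0.03) and TNFRSF10A (-0.92 ± 0.07) fell, and the pro-apoptotic BMF rose by 1.23 ± 0.26. The mitochondrially encoded mRNAs fell in 8 of 12 members (8 adjusted over the list alone), with small sizes such as CYTB at -0.38 ± 0.03, ND1 at -0.35 ± 0.07 and ND5 at -0.33 ± 0.05 (camera adjusted p = 2.16e-06). The adjusted p = 0.352 with an estimated correlation, and fry gave 0.0580.

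Of 33 cell cycle genes 19 rose and 4 fell (21 and 5 adjusted over the list alone), with a median log2 fold change of 0.21 (camera adjusted p = 2.06e-05, adjusted p = 0.0654 with an estimated correlation). CCNE2 rose from 16.7 ± 0.809 to 30.8 ± 0.691 CPM, CCNB2 from 63.3 ± 1.22 to 107.7 ± 6.65 CPM and CCNB1 from 166.5 ± 2.00 to 261 ± 2.71 CPM, all cyclins. Hypoxia and glycolysis genes rose in 17 of 28 members and fell in 4 (18 and 4 adjusted over the list alone, camera adjusted p = 5.12e-04, adjusted p = 0.242 with an estimated correlation). The glucose transporter gene SLC2A3 rose 6.87-fold (2.78 ± 0.17), SLC2A1 2.31-fold (1.21 ± 0.04) and EGLN3, which encodes a prolyl hydroxylase of hypoxia-inducible factors, 2.37-fold. Cholesterol synthesis genes rose in 12 of 23 members and fell in 4 (the numbers adjusted over the list alone were the same, camera adjusted p = 0.00571, adjusted p = 0.240 with an estimated correlation). SQLE, the gene of squalene epoxidase on chromosome 8, rose 8.42-fold (3.07 ± 0.09) and STARD4 1.58-fold.

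Receptor tyrosine kinase and EGFR ligand genes rose in 13 of 21 members and fell in 4 (13 and 5 adjusted over the list alone, camera adjusted p = 0.00491, adjusted p = 0.194 with an estimated correlation). RET rose by 1.71 ± 0.14, the EGFR ligand gene AREG by 1.32 ± 0.06 and IGF1R by 0.86 ± 0.13. Epithelial junction genes rose in 13 of 26 members and fell in 6 (14 and 6 adjusted over the list alone, camera adjusted p = 0.00369, adjusted p = 0.141 with an estimated correlation). The claudin genes CLDN3 (1.55 ± 0.24) and CLDN4 (0.77 ± 0.05) rose, as did ESRP1 (0.86 ± 0.04), a splicing regulator of epithelial cells on chromosome 8, and OVOL1 (0.83 ± 0.21). Mesenchymal genes went both ways, with 7 of 15 higher and 6 lower (8 and 6 adjusted over the list alone), and did not pass as a group (camera adjusted p = 0.381). Beside the fall of VIM, SNAI2 fell by 3.00 ± 0.50, while SPARC rose by 2.82 ± 0.25 and FN1, the fibronectin gene, rose from 13.9 ± 1.499 to 47.1 ± 3.78 CPM (1.76 ± 0.10).

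Transporters of platinum drugs changed little. SLC31A1, which encodes the copper transporter that also takes up platinum drugs, was lower in HCT116oxR (9.69 ± 2.39 to 7.15 ± 0.202 CPM, -0.44 ± 0.17, adjusted p = 0.0264). That call rested on single libraries, since without parental replicate 1 the log2 fold change was -0.23 and without HCT116oxR replicate 3 it was -0.42, neither past the threshold, and DESeq2 did not call it either (-0.44). ATP7B, a copper-exporting ATPase, rose from 19.8 ± 0.697 to 27.4 ± 1.51 CPM (0.47 ± 0.10). ATP7A stood at -0.38 ± 0.41 (adjusted p = 0.485) and ABCC2 at 0.16 ± 0.13 (adjusted p = 0.358). Of 10 tested members of the platinum transporter list, 1 rose and 1 fell, and 1 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.918).

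Of 11 ABC multidrug transporter genes 4 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.956). ABCG2 fell by 1.11 ± 0.20 and ABCC3 by 0.71 ± 0.05, and ABCA3 rose by 0.93 ± 0.12. ABCB1, the P-glycoprotein gene, was near the detection floor with 32, 20 and 15 parental and 10, 6 and 10 HCT116oxR counts (-1.41 ± 0.46, adjusted p = 0.00801). Its call was lost without parental replicate 1 (-1.11) and without HCT116oxR replicate 2 (-1.19). Among 13 glutathione S-transferase genes 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.430). GSTP1 rose from 194 ± 1.48 to 260.0 ± 21.9 CPM (0.43 ± 0.04) and MGST1 fell by 0.41 ± 0.05, and the near-identical GSTT2 (1.44 ± 0.29) and GSTT2B (1.04 ± 0.19) rose.

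The DNA repair lists did not pass as groups. Here and in the other lists, a member that lies in a shifted chromosome segment described below may move with that segment. Its change then cannot be read as one of its pathway alone. ERCC1, the nuclease partner that acts in the excision of platinum adducts, fell from 138 ± 6.81 to 83.7 ± 1.84 CPM (-0.73 ± 0.05, adjusted p = 8.00e-26). Of 30 nucleotide excision repair genes 11 fell and 1 rose (the numbers adjusted over the list alone were the same, camera adjusted p = 0.0749), among them RPA1 (-0.52 ± 0.07) and RAD23B (-0.50 ± 0.03). Of 33 Fanconi anaemia and homologous recombination genes 12 fell and 2 rose (the same adjusted over the list alone, camera adjusted p = 0.0866). XRCC3 fell by 0.53 ± 0.07 and MUS81 by 0.52 ± 0.08, and NBN (0.51 ± 0.05) and RAD54B (0.46 ± 0.06), both on chromosome 8, rose. Of 8 mismatch repair genes 2 fell and 1 rose (2 and 1 adjusted over the list alone, camera adjusted p = 0.182). PMS1 on chromosome 2 fell 5.89-fold, from 210.5 ± 3.92 to 35.7 ± 2.44 CPM, EXO1 fell by 0.48 ± 0.05 and MLH3 rose by 0.77 ± 0.17. Of 10 translesion polymerase genes 3 rose and 3 fell, by at most 0.45 ± 0.08 for POLI (camera adjusted p = 0.918), and 3 and 3 adjusted over the list alone, with a median of -0.00 and an upward mean of 0.02 and test.

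CDKN1A, which encodes the cell cycle inhibitor p21, fell from 331 ± 2.199 to 254 ± 3.79 CPM (-0.38 ± 0.04, adjusted p = 3.94e-18), whereas MDM2 stood at -0.06 ± 0.03 (adjusted p = 0.132).

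Among signalling lists that did not pass, Wnt targets and intestinal stem cell genes came closest, with 10 of 17 higher and 4 lower (10 and 5 adjusted over the list alone, camera adjusted p = 0.0545). The Wnt antagonist genes RNF43 (1.49 ± 0.04) and NOTUM (2.48 ± 0.19) rose and DKK1 fell by 1.15 ± 0.04. Integrated stress response and unfolded protein genes rose in 7 and fell in 10 of 25 members, also adjusted over the list alone (camera adjusted p = 0.0612), with ATF3 lower by 1.57 ± 0.09 and CRELD2 by 1.30 ± 0.08. YAP targets rose in 9 and fell in 8 of 21 members, also adjusted over the list alone (camera adjusted p = 0.988). ANKRD1 had 1 count over the parental and 122 over the HCT116oxR libraries (ratio of CPM 117, counting interval 20.5 to 4643) and CTGF fell from 46.0 ± 3.08 to 10.9 ± 0.967 CPM (-2.08 ± 0.10). MAPK output genes rose in 8 and fell in 6 of 21 members, also adjusted over the list alone (camera adjusted p = 0.956), with FOS at 1.43 ± 0.07 and DUSP4 at -1.34 ± 0.03. The MAPK list's median was 0.03, its mean -0.01 and its test downward.

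Of 17 fluoropyrimidine and thymidylate enzyme genes 5 rose and 6 fell (the same adjusted over the list alone, camera adjusted p = 0.412). UPP1, the uridine phosphorylase gene, fell from 196 ± 5.36 to 43.9 ± 3.53 CPM (-2.16 ± 0.05) and TYMP by 1.10 ± 0.11. Interferon-stimulated genes rose in 7 and fell in 9 of 30 members, and class I antigen presentation genes rose in 4 and fell in 3 of 13, both also when adjusted over the list alone (camera adjusted p = 0.852 and 0.743). Of the first list IFIT3 fell by 1.58 ± 0.27 and IFITM3 rose by 0.77 ± 0.06, and of the second HLA-B rose by 0.59 ± 0.06 and ERAP1 fell by 1.09 ± 0.13. The interferon list's median was -0.07, its mean 0.01 and its test downward. Of 6 tested intestinal differentiation genes 2 rose and 2 fell (also adjusted over the list alone, camera adjusted p = 0.674), with KLF4 at -1.29 ± 0.08. Among 5 cancer-testis genes PRAME rose by 0.37 ± 0.07 and was the 1 member to change, also adjusted over the list alone (camera adjusted p = 0.450).

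Markers of other cell types and of RNA handling were measured beside these groups. Of 5 tested fibroblast and smooth muscle genes TAGLN rose by 1.49 ± 0.13 and COL1A1 fell by 0.30 ± 0.07 (camera adjusted p = 0.852), and 1 and 1 changed adjusted over the list alone, with a median of -0.30, a mean of 0.14 and an upward test. Of 3 liver and kidney genes PAX2 rose by 1.52 ± 0.15 (1 higher over all genes and 2 adjusted over the list alone, camera adjusted p = 0.182). Of 3 genes of breast, cervical, lung and neural lines NKX2-1 (1.70 ± 0.47) and NAPSA (1.31 ± 0.35) rose, both at under 4 CPM, and 2 rose adjusted over the list alone (camera adjusted p = 0.430). The leukocyte and endothelial list had too few tested members for a test, and of these CD68 fell by 1.09 ± 0.17 while VWF stood at 0.74 ± 0.34. Of 21 replication-dependent histone genes, whose mRNAs lack a poly(A) tail, 2 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.430).

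In total RNA most short non-coding genes did not pass. Of 246 tested snoRNA genes, which guide the modification of ribosomal RNA, 81 rose and 6 fell, with a median log2 fold change of 0.35, and the count was 80 to 84 higher and 6 lower under the other scalings. Of 17 snRNA genes 7 fell and 0 rose (median -0.74), and of 28 tRNA genes 6 fell and 0 rose (median -0.18). Of 245 miRNA genes in total RNA 31 rose and 10 fell (median 0.08). Tested against a fold of 1.5, 8 snoRNA genes remained. Of 14 small structured RNAs fixed as signs of rRNA depletion and fragment size, 4 rose and 4 fell (4 and 5 adjusted over the list alone, camera adjusted p = 0.604). RN7SK, the scaffold RNA of the P-TEFb kinase, fell from 8159 ± 404 to 4886 ± 441 CPM (-0.74 ± 0.08), and RMRP, the RNA of RNase MRP, rose from 1486 ± 119 to 2148 ± 74.0 CPM (0.53 ± 0.06). Many snoRNA genes lie in introns of host genes, and such overlapping reads cannot be separated here.

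A line kept under selection can differ from its parent in whole chromosome segments, so protein-coding genes were grouped by position (GRCh38). On chromosome 2 between 180 and 190 Mb all 24 tested genes fell, with a median log2 fold change of -1.86, a 3.64-fold drop (camera adjusted p = 1.24e-39, adjusted p = 0.132 with an estimated correlation). On chromosome 22 beyond 50 Mb 25 of 26 genes fell and 0 rose (median -1.17, camera adjusted p = 8.08e-21, adjusted p = 0.119 with an estimated correlation). On chromosome 8 the windows from 80 to 150 Mb were higher, with medians of 0.45 to 0.77 and adjusted p = 0.422 to 0.553 with an estimated correlation, and in the window from 90 to 100 Mb 35 of 38 genes rose and 0 fell (camera adjusted p = 1.99e-20, adjusted p = 0.422 with an estimated correlation). The long arm of chromosome 9 was lower in the windows from 70 to 80 and from 90 to 140 Mb, with medians from -0.28 to -0.40 and adjusted p = 0.422 to 0.722 with an estimated correlation. In the window from 120 to 130 Mb 66 of 108 genes fell and 4 rose (camera adjusted p = 6.82e-08, adjusted p = 0.422 with an estimated correlation).

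In all, 21 of 285 windows passed, 11 higher and 10 lower, and 0 passed with an estimated correlation. As whole chromosomes, 8 was higher (median 0.30, 228 of 430 genes rose and 68 fell, adjusted p = 0.103 with an estimated correlation) and 9 lower (median -0.21, 251 of 515 fell and 53 rose). The call of chromosome 9 held with an estimated correlation (adjusted p = 0.00485), and none of the other chromosomes tested passed, of 23 in all. The remaining windows lay on chromosome 17, lower from 0 to 10 Mb (83 of 160 fell, median -0.28, adjusted p = 0.577 with an estimated correlation) and higher from 70 to 80 Mb (57 of 92 rose, median 0.32, adjusted p = 0.489 with an estimated correlation). Smaller medians stood on chromosome 2 from 170 to 180 Mb (-0.18) and 220 to 230 Mb (0.33), each with adjusted p = 0.422 with an estimated correlation, and on chromosome 5 from 30 to 40 Mb (0.19, adjusted p = 0.696 with an estimated correlation). The window from 170 to 180 Mb mixes genes before and inside the segment that starts at 175.9 Mb (described below). Its median is therefore not the size of a separate shift. The window on chromosome 17 from 80 to 90 Mb (0.15, adjusted p = 0.963 with an estimated correlation) lost its call without parental replicate 1 (0.12), parental replicate 2 (0.15) or HCT116oxR replicate 2 (0.12). The window on chromosome 9 from 90 to 100 Mb lost its call without HCT116oxR replicate 2 (-0.28).

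**Figure D3:**
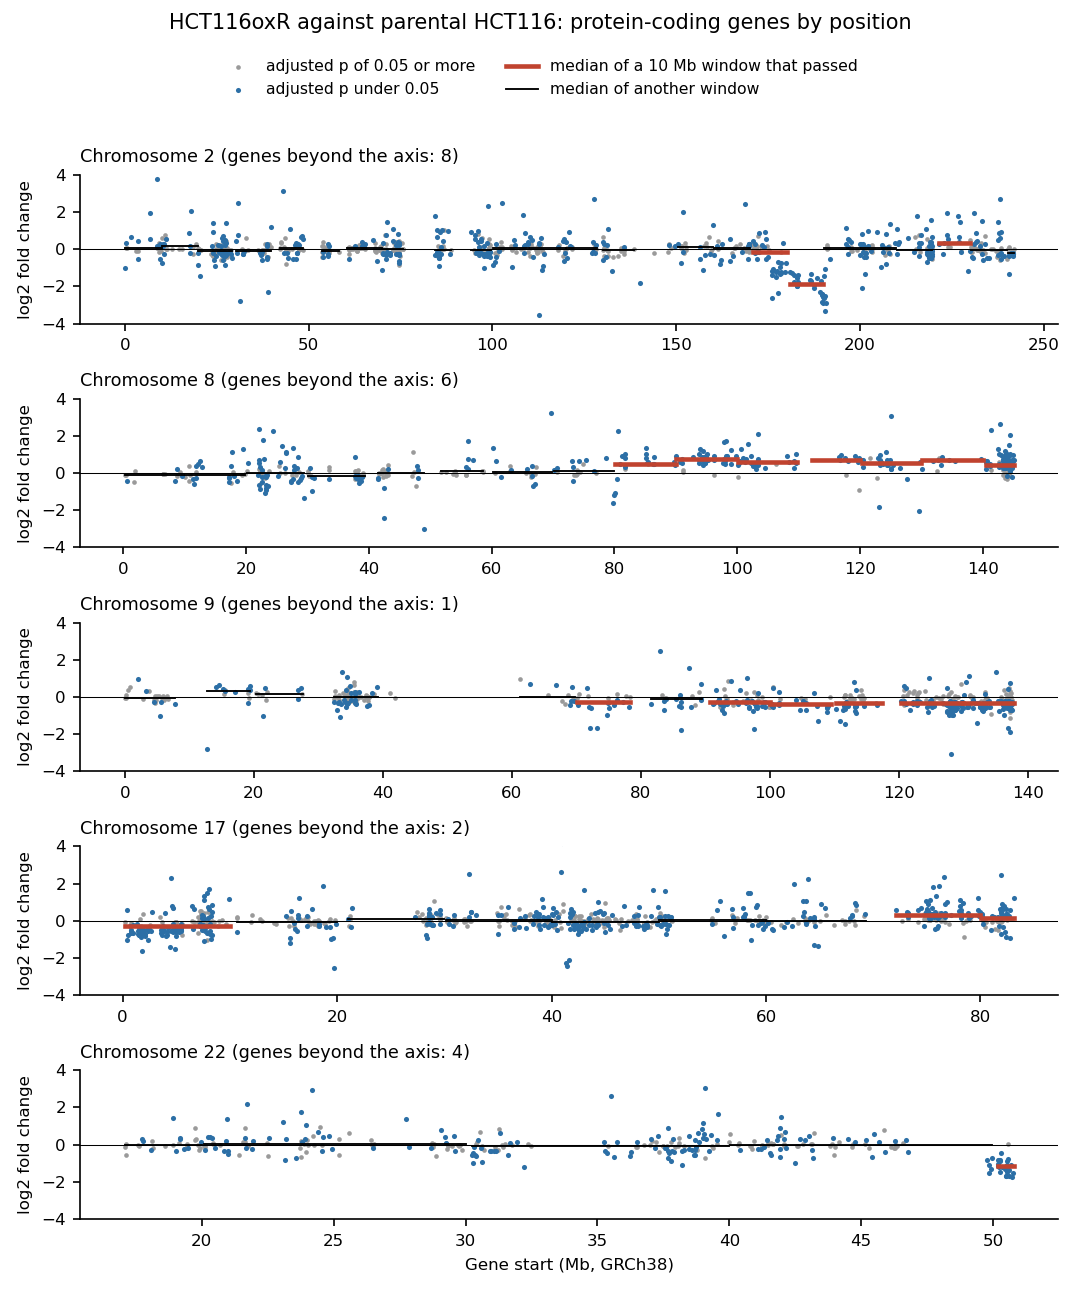
Log2 fold change in HCT116oxR over parental cells (vertical axis) of each tested protein-coding gene against its start in Mb (GRCh38, horizontal axis) on chromosomes 2, 8, 9, 17 and 22, blue where the gene passed the adjusted threshold and grey where it did not. Red lines are medians of 10 Mb windows that passed and black lines those of other windows, and the windows at -1.86 on chromosome 2 and -1.17 on chromosome 22 stand furthest from 0.

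In small RNA the same comparison was made for mature miRNAs. miR-224-5p rose from 1.59 ± 0.640 to 221 ± 14.7 CPM (log2 fold change 7.11 ± 0.17, SE, n = 3 per line) and miR-452-5p from 0.465 ± 0.321 to 75.3 ± 0.225 CPM (7.33 ± 0.21). Both lie in introns of GABRE. miR-10b-5p, encoded in the HOXD cluster on chromosome 2, fell from 3665 ± 43.5 to 883.6 ± 106 CPM (-2.05 ± 0.08), miR-22-3p from 2263 ± 51.2 to 653 ± 6.71 CPM (-1.79 ± 0.05) and miR-192-5p from 648 ± 14.1 to 173 ± 3.74 CPM (-1.90 ± 0.05). miR-135b-5p rose 2.55-fold, from 177 ± 12.02 to 450.3 ± 58.4 CPM, and miR-135b-3p 3.19-fold.

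Of 975 tested miRNAs 436 changed (edgeR, Benjamini-Hochberg adjusted), 229 higher and 207 lower, with 65 higher and 100 lower by at least 2-fold. All libraries of the lines were apart for 538 miRNAs (55.2%, where chance gives 10%). With upper quartile scaling 191 were higher and 258 lower, which moved the share of higher calls from 52.5% to 42.5%. Tested against a fold of 1.5, 138 remained past the threshold, and with the stricter filter on low counts 271 changed. Further rises were those of miR-1252-5p (2.88 ± 0.11), miR-483-3p (2.45 ± 0.13), which lies in IGF2, miR-629-5p (1.46 ± 0.06) and miR-95-3p (1.42 ± 0.07). Further falls were those of miR-561-5p (-2.36 ± 0.20), miR-10b-3p (-2.36 ± 0.14), miR-22-5p (-1.94 ± 0.12), miR-4456 (-1.48 ± 0.14) and miR-205-5p (-1.43 ± 0.16). The miR-22 gene lies in MIR22HG, in the chromosome 17 window from 0 to 10 Mb that passed as lower. As for genes, a miRNA encoded in a shifted segment may move with that segment. Its change then cannot be read as one of that miRNA alone.

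Of the miRNAs named whatever their test, miR-34a-5p fell from 319 ± 5.32 to 271 ± 9.66 CPM (-0.23 ± 0.06, adjusted p = 0.00478), and this call was lost without HCT116oxR replicate 2 (-0.18). miR-200c-3p, a repressor of ZEB1, rose from 12465 ± 103 to 14140 ± 725 CPM (0.18 ± 0.05, adjusted p = 0.00706), and was not called with upper quartile scaling. miR-203a-3p stood at 0.17 ± 0.07 (adjusted p = 0.0521), passing without a filter on low counts (0.20) and without HCT116oxR replicate 3 (0.25), and miR-31-5p at -0.08 ± 0.04 (adjusted p = 0.148). miR-21-5p was slightly lower (-0.13 ± 0.04, adjusted p = 0.0159). Its call was lost with DESeq2 (-0.14), without a filter on low counts (-0.10) and without parental replicates 1 (-0.14), 2 (-0.09) and 3 (-0.12) or HCT116oxR replicates 1 (-0.09) and 2 (-0.08) in turn.

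**Figure D4:**
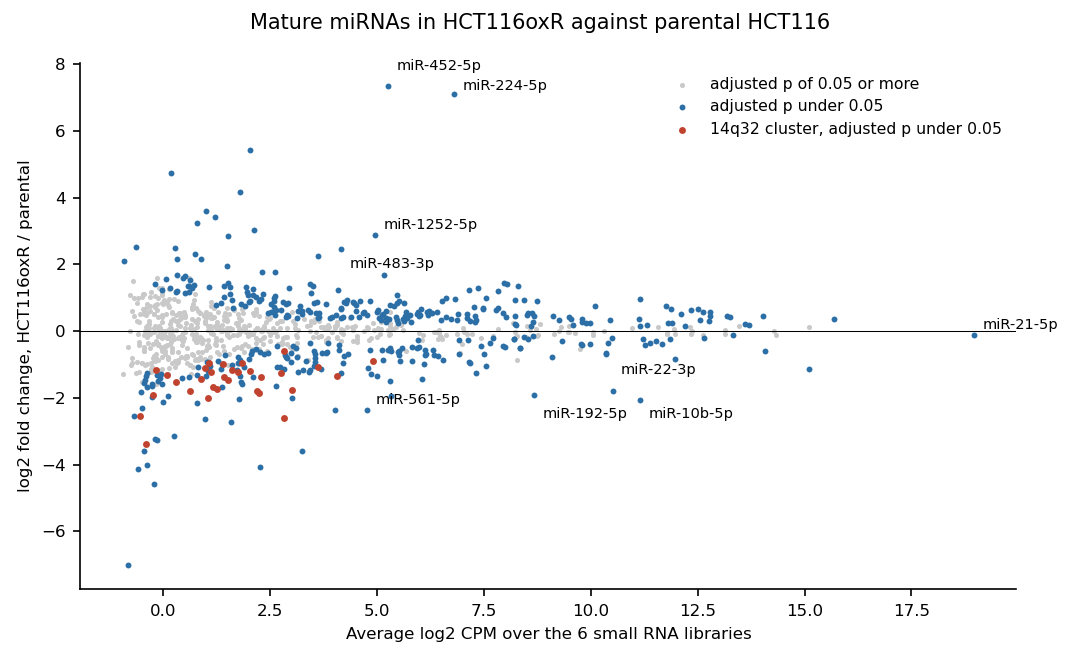
Log2 fold change in HCT116oxR over parental cells (vertical axis) of each of 975 tested miRNAs against its average log2 CPM over the 6 small RNA libraries (horizontal axis). Points are grey where the miRNA did not pass the adjusted threshold, blue where it did and red for members of the 14q32 cluster that did, all 31 of which lie below 0.

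Lists of miRNAs fixed by family or cluster were tested in the same way. The miRNAs of the imprinted 14q32 cluster fell together, with 31 of 40 tested members lower, 0 higher and 26 lower by at least 2-fold (median -1.28, camera adjusted p = 2.44e-08). Adjusted over the list alone 35 fell, and the call was lost with adjusted p = 0.133 with an estimated correlation. All 3 tested members of the miR-224 and miR-452 list rose, also adjusted over the list alone (camera adjusted p = 0.00259, adjusted p = 0.133 with an estimated correlation). The miR-17-92 and paralogous clusters, growth-promoting targets of MYC and E2F, rose in 10 of 21 members and fell in 0 (11 adjusted over the list alone, camera adjusted p = 0.00259, adjusted p = 0.133 with an estimated correlation), with miR-18a-5p at 1.00 ± 0.07 and miR-17-5p at 0.66 ± 0.04. The miR-200 family, which maintains the epithelial state, rose in 6 of 9 members and fell in 1, also adjusted over the list alone (camera adjusted p = 0.00997, adjusted p = 0.133 with an estimated correlation), with miR-429 at 0.95 ± 0.06 and miR-200a-3p at 0.46 ± 0.05. The miR-100, let-7 and miR-125 clusters rose in 10 of 16 members and fell in 1 (11 and 1 adjusted over the list alone, camera adjusted p = 0.00883, adjusted p = 0.133 with an estimated correlation), with miR-99b-5p at 0.76 ± 0.04.

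The miR-15/16 family fell in 9 of 13 members and rose in 0 (11 fell adjusted over the list alone, camera adjusted p = 0.00259, adjusted p = 0.133 with an estimated correlation), with miR-424-5p at -1.24 ± 0.14 and miR-15a-5p at -0.85 ± 0.09. The miR-23, miR-27 and miR-24 clusters fell in 6 of 11 members and rose in 1, also adjusted over the list alone (camera adjusted p = 0.0401, adjusted p = 0.172 with an estimated correlation), and without parental replicate 2 the adjusted p was 0.0514. miR-27a-3p fell from 5088 ± 194 to 2874 ± 295 CPM (-0.82 ± 0.07).

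Of the lists that did not pass, the let-7 family had 6 of 19 members lower and 2 higher (5 and 2 adjusted over the list alone, camera adjusted p = 0.0696), with let-7i-5p falling from 47966 ± 1004 to 21928 ± 1804 CPM (-1.13 ± 0.06). In the miR-371 to miR-373 and miR-302 clusters 4 of 10 members fell by at least 2-fold and 0 rose, also adjusted over the list alone (camera adjusted p = 0.0546). The miR-221 and miR-222 list rose in 3 of 4 members (camera adjusted p = 0.0620), the miR-30 family rose in 5 and fell in 2 of 11 (0.130), and the miR-181 family rose in 1 and fell in 4 of 9 (0.0609), the same numbers each adjusted over the list alone. The cluster of miR-183, miR-96 and miR-182 fell in 4 of 6 (0.0696) and the miR-29 family rose in 2 of 7 (0.342), also adjusted over the list alone. HOX cluster miRNAs rose in 3 and fell in 3 of 10 (0.408), also adjusted over the list alone, with a median of 0.08, a mean of -0.24 and a downward test. The miR-148 and miR-152 family rose in 2 and fell in 2 of 6, also adjusted over the list alone (0.615), and the primate cluster on chromosome 19 fell in 2 of 3, or 3 adjusted over the list alone (0.118). Of 50 miRNAs described in colorectal cancer and drug response 22 rose and 10 fell (23 and 11 adjusted over the list alone, camera adjusted p = 0.118). The list of miR-210, the miRNA induced by hypoxia, had too few members for a test, and miR-210-3p rose by 0.36 ± 0.05.

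Markers of other cell types were measured in small RNA too. Mesenchymal miRNAs rose in 4 of 8 members and fell in 0, also adjusted over the list alone (camera adjusted p = 0.0187, adjusted p = 0.133 with an estimated correlation), with miR-145-5p at 1.29 ± 0.09. Blood miRNAs rose in 3 of 4, also adjusted over the list alone (camera adjusted p = 0.0401, adjusted p = 0.172 with an estimated correlation), led by miR-142-3p at 2.25 ± 0.15. That list's adjusted p rose above the threshold without each of 5 libraries in turn, to 0.0830, 0.0607 and 0.0607 without parental replicates 1, 2 and 3 and to 0.0560 and 0.116 without HCT116oxR replicates 2 and 3. Of 7 liver, muscle, neural and endothelial miRNAs 2 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.135). With the stricter filter on low counts 3 of the 10 miRNA lists that passed were still called (1 of the 10 is left undescribed here), those of miR-17-92, of the miR-15 and miR-16 family and of the 14q32 cluster.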

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

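The fit without the genes of the windows that passed was chosen after the data had been seen. It gave 6811 changed genes and 11 lists, 10 of them shared. Against a fold of 1.5, glmTreat gave 1430 genes, 200 lncRNAs and 138 miRNAs, since it asks for larger changes. The stricter filter on low counts gave 271 miRNAs and 3 miRNA lists, with fewer miRNAs tested. With an estimated correlation camera called 2 gene lists, 0 miRNA lists and 0 windows, and fry, which compares a list with no other genes, called 25 and 22 lists. Leaving out 1 library at a time gave 6994 to 7275 genes, 556 to 578 lncRNAs, 361 to 445 miRNAs, 10 to 13 gene lists, 9 to 13 miRNA lists and 20 to 22 windows. DESeq2 gave 6780 genes, 510 lncRNAs and 386 miRNAs. No named gene or miRNA that had passed changed direction with another scaling, without a low count filter, with DESeq2, limma-voom or the block, or without 1 library. The medians of the lists of mismatch repair, translesion polymerase, fluoropyrimidine, stress response and HOX cluster members changed sign with the scaling. Genes with few counts were limited by depth. miRNA seed sites were not run.

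With a block for the replicate number there were 7565 genes, 600.0 lncRNAs, 405 miRNAs and 12 and 11 lists. With camera the block added the calls of Wnt targets (adjusted p = 0.0445), stress response genes (0.0299) and miR-221 and miR-222 (0.0490). No shared effect of the replicate number was visible. Deviations from the line means of libraries with the same number correlated across genes at -0.007, -0.013 and -0.027 in total RNA and 0.079, -0.043 and -0.144 in small RNA. Whether cultures with the same number were handled together is not stated.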

Other observations

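The tests of DNA copy number, of short RNA and of mesenchymal cells, the search for runs of neighbouring genes and the genes named beside them were chosen only after the results were seen. The segment that fell on chromosome 2 had sharp ends (GRCh38). Counting as a run at least 10 successive protein-coding genes whose running median of 5 genes lay beyond 0.4 (log2), a run reached from KIAA1715 at 175.9 Mb to NAB1 at 190.7 Mb, in which 47 of 49 genes fell and 1 rose, with a median log2 fold change of -1.56. The 6 genes before it had a median of 0.06 and the 6 after it 0.08. At its edges ATP5G3 stood at -0.07 ± 0.05 (SE, n = 3 per line) and KIAA1715 at -1.41 ± 0.04, and NAB1 at the far edge stood at -2.88 ± 0.04. The run holds PMS1, TTN, the integrin gene ITGAV (-1.73 ± 0.04) and NFE2L2 (-1.51 ± 0.04), which encodes NRF2, the transcription factor behind the NRF2 target list. A link between NFE2L2 and its targets was not tested. On chromosome 22 a run from BRD1 at 49.8 Mb to RABL2B at 50.8 Mb had 30 of 31 genes lower and a median of -1.14, and the 6 genes before it had a median of 0.02. In all there were 17 runs of 373 genes, the longest of 70 genes on chromosome 8, while 1000 shuffles of gene positions gave at most 3 runs and none longer than 16 genes.

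Host transcripts and their miRNAs were measured in different libraries. GABRE was at least 10.96-fold higher and hsa-miR-224-5p rose by 7.11 ± 0.17, MIR17HG rose by 0.96 ± 0.18 and hsa-miR-17-5p by 0.66 ± 0.04, and MIR22HG fell by 1.35 ± 0.19 and hsa-miR-22-3p by 1.79 ± 0.05. MIR31HG fell by 1.20 ± 0.33 while hsa-miR-31-5p stood at -0.08 ± 0.04.

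Genes that lie next to each other shifted together in 21 windows, of which 0 passed with an estimated correlation. A trend with expression level or gene span was argued against as the whole cause, since taking it out moved 2199 of 12608 genes by over 0.1 (log2) and the median of no window that passed by more than 0.07, and 21 of 21 windows were still called in the same direction. A difference in DNA copy number between the lines is a candidate explanation that the small RNA libraries were consistent with, since single-locus miRNAs in windows called higher and lower differed by 0.783 in median log2 fold change (bootstrap interval 0.364 to 1.38, 2-sided permutation p = 0.00034 with 100000 resamples). The shuffles and resamples took 25 loci in higher and 34 in lower windows as independent. Many of these loci share a segment, so the p-value may be too small and the interval too narrow. Regulation shared along a segment would shift both kinds of RNA too and stays open, as does GC content, which was not tested.

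The rise of snoRNA genes was set against other short genes. A higher yield of short RNA in the HCT116oxR libraries was argued against, since 426 other tested genes of at most 200 nt had a median of 0.0057 (interval -0.07 to 0.06) and the snoRNA genes 0.35 (0.28 to 0.41). That comparison is limited, since miRNA genes, of which 245 were tested in total RNA, may hold reads of longer overlapping transcripts. Of the 17 snRNA genes (median -0.74) and 28 tRNA genes (median -0.18), 0 rose. Whether transcription of the host genes accounts for the whole rise could not be decided. Over 128 hosts the snoRNA exceeded its host by a median of 0.126 (0.0478 to 0.233). That interval lies above 0 but reaches below the 0.1 set as the bound. The hosts themselves had a median of 0.123 (0.0406 to 0.194), with 60 higher and 23 lower. A biological difference between the lines stays open and untested.

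The fall of the 14q32 miRNAs was weighed against copy number, low abundance and other cells. A copy number change of the wider region was argued against, since 64 protein-coding genes within 5 Mb had a median of 0.0927 (interval -0.00290 to 0.187) beside -1.28 for the miRNAs. A change confined to the cluster, or in which parental copy is kept, would not show in those genes and was not tested. Low abundance was argued against too, since the cluster's median lay at percentile 0 of 10000 lists matched on level, the lowest of which had -0.70. Whether the HCT116oxR cultures held fewer mesenchymal cells could not be decided. The 8 mesenchymal miRNAs had a median of 0.605 (interval 0.0314 to 1.29), with 4 higher and 0 lower. Of 15 mesenchymal genes in total RNA, however, 7 rose, FN1 among them, and 6 fell, VIM among them. Altered transcription of the imprinted cluster may account for the fall and was not tested.

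The 6 libraries of each kind form 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 7721 changed genes, 623 changed lncRNAs and 436 changed miRNAs, where the highest of the other splits gave 0 for each, so that 1 split reached each of these counts. It gave 10 lists in total RNA, where the highest other gave 5, and 10 lists in small RNA, where the highest other gave 2. For windows 2 splits, the real one included, gave at least 21, the highest other giving 23. Each of the other splits sets libraries of both lines on both sides, so part of the real difference remains in them and they do not show values without change.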
